A study of Mus musculus with 6 samples.

How the data were processed

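Poly(A) RNA of heart ventricle from C57BL6 mice aged 6 to 8 weeks or 24 to 26 months was sequenced as paired reads of 100 bases, per the labels, with 3 libraries from separate samples per age. Samples were grouped by the age in their labels, and the labels do not say whether each sample came from its own mouse. The authors deposited 1 table with FPKM, fragments scaled to transcript length and to the mapped fragments of a library, for 18181 genes in all 6 libraries, to 2 decimals, per the file headers. The submitters' processing notes list HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build mm10 without saying how they were used; the annotation and any filter are not given in the sources used here. No strand marking is stated, so reads of overlapping or antisense genes are not told apart. Of the genes, 277 were at 0 in every library and the smallest value above 0 was 0.01. Low values showed no steps of whole reads, so read counts were not recovered, depth is unknown and no counting interval is given; a value of 0 is described as listed at 0.

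Gene IDs were matched to a RefSeq gene table of GRCm38.p6, the assembly called mm10, for coordinates (18128 of the IDs, 99.7%); 18014 of the genes were protein-coding. The table has no row for Igkc, Xist or the mitochondrially encoded genes, which were not analysed here. The same holds for the other listed immunoglobulin genes and for Trac, Trbc1 and Trbc2. Transcript length and GC content came from GENCODE vM21 for 11736 of the tested genes (99.0%) and for 100% of the matrix genes. The main comparison was aged minus young with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend) on log2(FPKM + 1), two-sided, for the 11860 genes with a mean of at least 1 FPKM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes, while folds are ratios of mean FPKM. An exact permutation test of 3 against 3 cannot give a p below 0.1, so calls rest on the spread that limma pools across genes. On simulated data of this comparison with 11860 genes and 200 changed, the same steps recovered 88% of changes of log2 1 and 57% of those of log2 0.5, all with the right sign, and 2.68% of the 149 calls were false. The simulated noise was independent between genes. It does not cover genes that vary together, a library unlike its group, or the 26.4% of genes called in the real data, so these shares need not hold there.

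For gene lists, 37 were fixed before the data were examined, and the 33 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 33. Beside it stand camera with a correlation estimated from each list, camera on ranks (19 lists called) and fry, which tests a list by itself. For each list the members called over all genes and adjusted over the list alone were counted. Named genes followed a rule set at the same time. They are the 10 largest called differences in each direction whose ages do not overlap, leaving out predicted gene models (30 among the higher and 34 among the lower), up to 4 called members of each list with the largest statistic (or the 2 with the smallest p where none was called), and a fixed set of heart and ageing genes. Other genes, named to complete a count of 5 or fewer or in the closing section, were chosen after their values were seen. Some genes that the rule or a count covers are not reported here.

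The alternatives set before the data were examined were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, TPM, median-of-ratios and quantile scaling, a prior variance without a trend, robust empirical Bayes, library quality weights, a replicate block, leaving out each library, and a minimum log2 difference of 1. Further alternatives chosen after seeing the data were removal of each library's trend on transcript length and GC content (a spline with 4 degrees of freedom), leaving out aged replicates 1 and 2 together, and leaving out 302 genes over 4 times higher in both of these than in each other library. Additional lists, also chosen after the data had been seen, were stratified epithelium, neutrophil genes without S100a8 and S100a9, hepatocyte, salivary gland and pancreas, kidney, large vessel smooth muscle, imprinted growth network, glucocorticoid response, xenobiotic metabolism and pluripotent stem cell. Intervals of list medians are 95% bootstrap intervals over genes from 10000 resamples. They treat genes as independent and do not measure the spread between samples. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.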

Results

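Messenger RNA was profiled from heart ventricle of C57BL6 mice, an inbred laboratory strain, at 6 to 8 weeks, called young here, and at 24 to 26 months, called aged. Each age had 3 libraries from separate samples, so the table held 6 libraries and 18181 genes, with expression given in FPKM, fragments scaled to transcript length and to the mapped fragments of a library. The labels do not say whether each sample came from its own mouse, so p-values measure only the spread between these samples. The FPKM values of a library summed to 529258 (young replicate 3) to 566499 (aged replicate 1), and between 15750 and 16232 genes had a value above 0. FPKM carry no read totals, so the depth of each library is unknown and no counting interval is given. Principal components of the tested genes separated the ages along the first, which held 67.4% of the variance. Aged replicate 3 lay at 11.3 on it, aged replicates 1 and 2 at 26.4 and 28.6, and the young libraries between -24.4 and -17.8. Correlations across genes, which are not independent replicates, were 0.981 to 0.995 between libraries of an age and 0.96 to 0.979 between ages. Of 4 sex-linked genes tested, 0 were called by limma, over all genes or adjusted over the list alone. The Y-linked gene Ddx3y was at 16.9 ± 0.577 FPKM in young and 17.3 ± 0.745 in aged (SD, n = 3), and Eif2s3y at 35.8 ± 2.67 and 35.5 ± 2.804. The sign of so small a difference turned with the scaling, for Ddx3y on TPM and for Eif2s3y with median-of-ratios and quantile scaling.

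**Figure D1:**
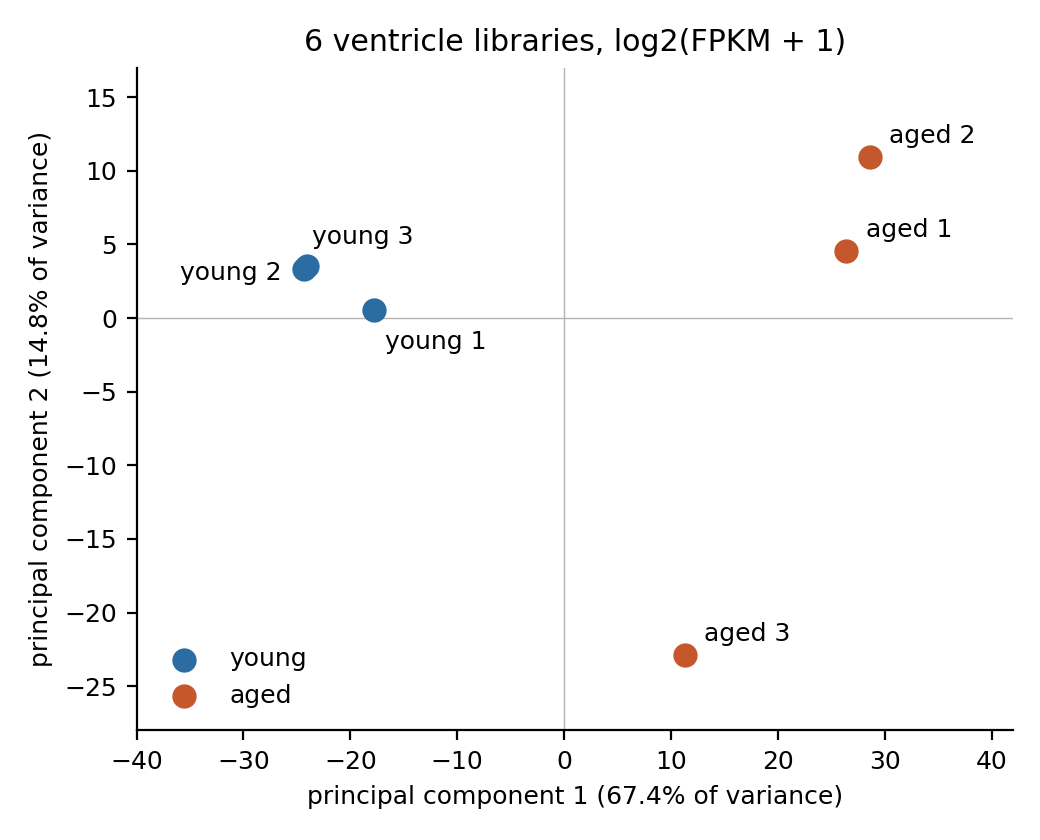
The 6 libraries on the first 2 principal components of log2(FPKM + 1) over the 11860 tested genes; each point is a library, blue for young and orange for aged, and the axes give component scores with the percentage of variance in brackets. The first component separates the ages, and aged replicate 3, at 11.3, lies between the other aged libraries and the young ones and apart from both on the second component, at -22.9.

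The comparison asked which transcripts differ in the ventricle between young adult and old mice. With the preset correlation of limma's camera, old ventricle had less messenger RNA for the lists of matrix, basement membrane, cell division and interferon-stimulated genes, and more for those of fatty acid oxidation, antioxidant genes, complement and chemokines. With a correlation estimated from these libraries camera called 0 of the 33 lists (smallest adjusted p = 0.403, 3 at an unadjusted p under 0.05), while limma's fry called 19. Of 11860 genes tested, 1105 were higher and 2026 lower in aged ventricle (limma, adjusted p under 0.05), and 140 and 160 of these differed by a log2 difference of at least 1. In 1095 of the higher and 2011 of the lower genes the 3 aged libraries lay wholly above or below the 3 young ones; over all tested genes 43.0% were separated in this way, where chance gives 10%. The share of higher genes among the calls was 35.3%, but 28.2% after rescaling to TPM (977 higher, 2489 lower), 49.6% with median-of-ratios scaling (1484 and 1506) and 46.7% with quantile normalization (1316 and 1500). The median log2 difference of all tested genes was -0.06 as deposited, -0.10 on TPM, -7e-04 with median-of-ratios scaling and -0.0048 with quantile normalization. Transcripts of stratified epithelium stood in aged replicates 1 and 2: Krt13, a keratin of such epithelia named after its values were seen, was at 152 and 250.3 FPKM there and listed at 0 in the other 4 libraries. With aged replicate 3 alone against the 3 young libraries, a fit chosen after seeing the data in which the lone sample is assumed to vary like the others, 420 genes were higher and 552 lower. Without young replicate 3 the counts were 718 and 1164, and without young replicate 2 they were 814 and 1242.

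Among the 10 largest rises were genes of muscle and of metabolism. Cpxm2, a carboxypeptidase family member (chromosome 7, 132032687 to 132154765, GRCm38), went from 1.82 ± 0.713 to 40.2 ± 9.55 FPKM (SD, n = 3), 22.1-fold, with a log2 difference of 3.87 (SE 0.195, adjusted p = 1.38e-05). Myot, which encodes the Z-disc protein myotilin (chromosome 18, 44334053 to 44355740), rose from 6.44 ± 0.913 to 85.5 ± 1.94 (3.55, SE 0.0914, adjusted p = 2.13e-07). Scn4b, a beta subunit of the sodium channel (chromosome 9, 45138624 to 45154155), rose from 2.67 ± 0.372 to 34.1 ± 1.33 (3.26, SE 0.0889, adjusted p = 2.13e-07). The amylase gene Amy1 rose from 1.36 ± 0.407 to 24.7 ± 4.05 and the methyltransferase gene Inmt from 1.05 ± 0.679 to 19.4 ± 0.652. Bdh1, an enzyme of ketone body use, rose from 12.6 ± 7.51 to 108 ± 20.6. Amy1 has close gene copies with which reads can be shared. Ccl8, a chemokine, was at 0.23, 0 and 1.01 FPKM in the young libraries and 8.89, 7.74 and 12.4 in the aged, and Strit1, which encodes a small activator of the sarcoplasmic calcium pump, rose from 12.5 ± 3.94 to 95.5 ± 19.8. Sprr1a, a cornified envelope gene that injured heart muscle also expresses, was at 12.5, 17.8 and 2.36 FPKM in aged replicates 1 to 3 and at 0, 0.43 and 0.13 in young; its 2 highest values lay in the libraries with keratin transcripts.

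The 10 largest falls included genes of the matrix list (Eln, Col3a1 and Sparc). Casq1, the calcium-storing calsequestrin typical of fast skeletal muscle (chromosome 1, 172209894 to 172219895), fell from 33.3 ± 3.85 to 1.91 ± 0.121 FPKM (SD, n = 3), 17.4-fold, with a log2 difference of -3.55 (SE 0.0949, adjusted p = 2.13e-07). Acta2, smooth muscle alpha-actin (chromosome 19, 34240336 to 34255585), fell from 543 ± 85.4 to 60.1 ± 17.5 (-3.19, SE 0.202, adjusted p = 2.84e-05); its coding sequence is close to that of other actins. Eln, which encodes elastin (chromosome 5, 134702595 to 134747368), fell from 94.8 ± 13.7 to 14.2 ± 2.35 (-2.66, SE 0.1299, adjusted p = 1.18e-05). The imprinted gene Mest fell from 21.4 ± 8.38 to 3.28 ± 0.995, the secreted C1q-family gene C1qtnf6 from 26.9 ± 2.41 to 4.703 ± 0.873, and the amino acid transporter gene Slc38a1 from 5.29 ± 0.607 to 0.56 ± 0.108. Kcne1, a potassium channel subunit, fell from 6.95 ± 1.62 to 0.993 ± 0.0757. Col3a1, Sparc and Mfap4, described with their groups, were the others.

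**Figure D2:**
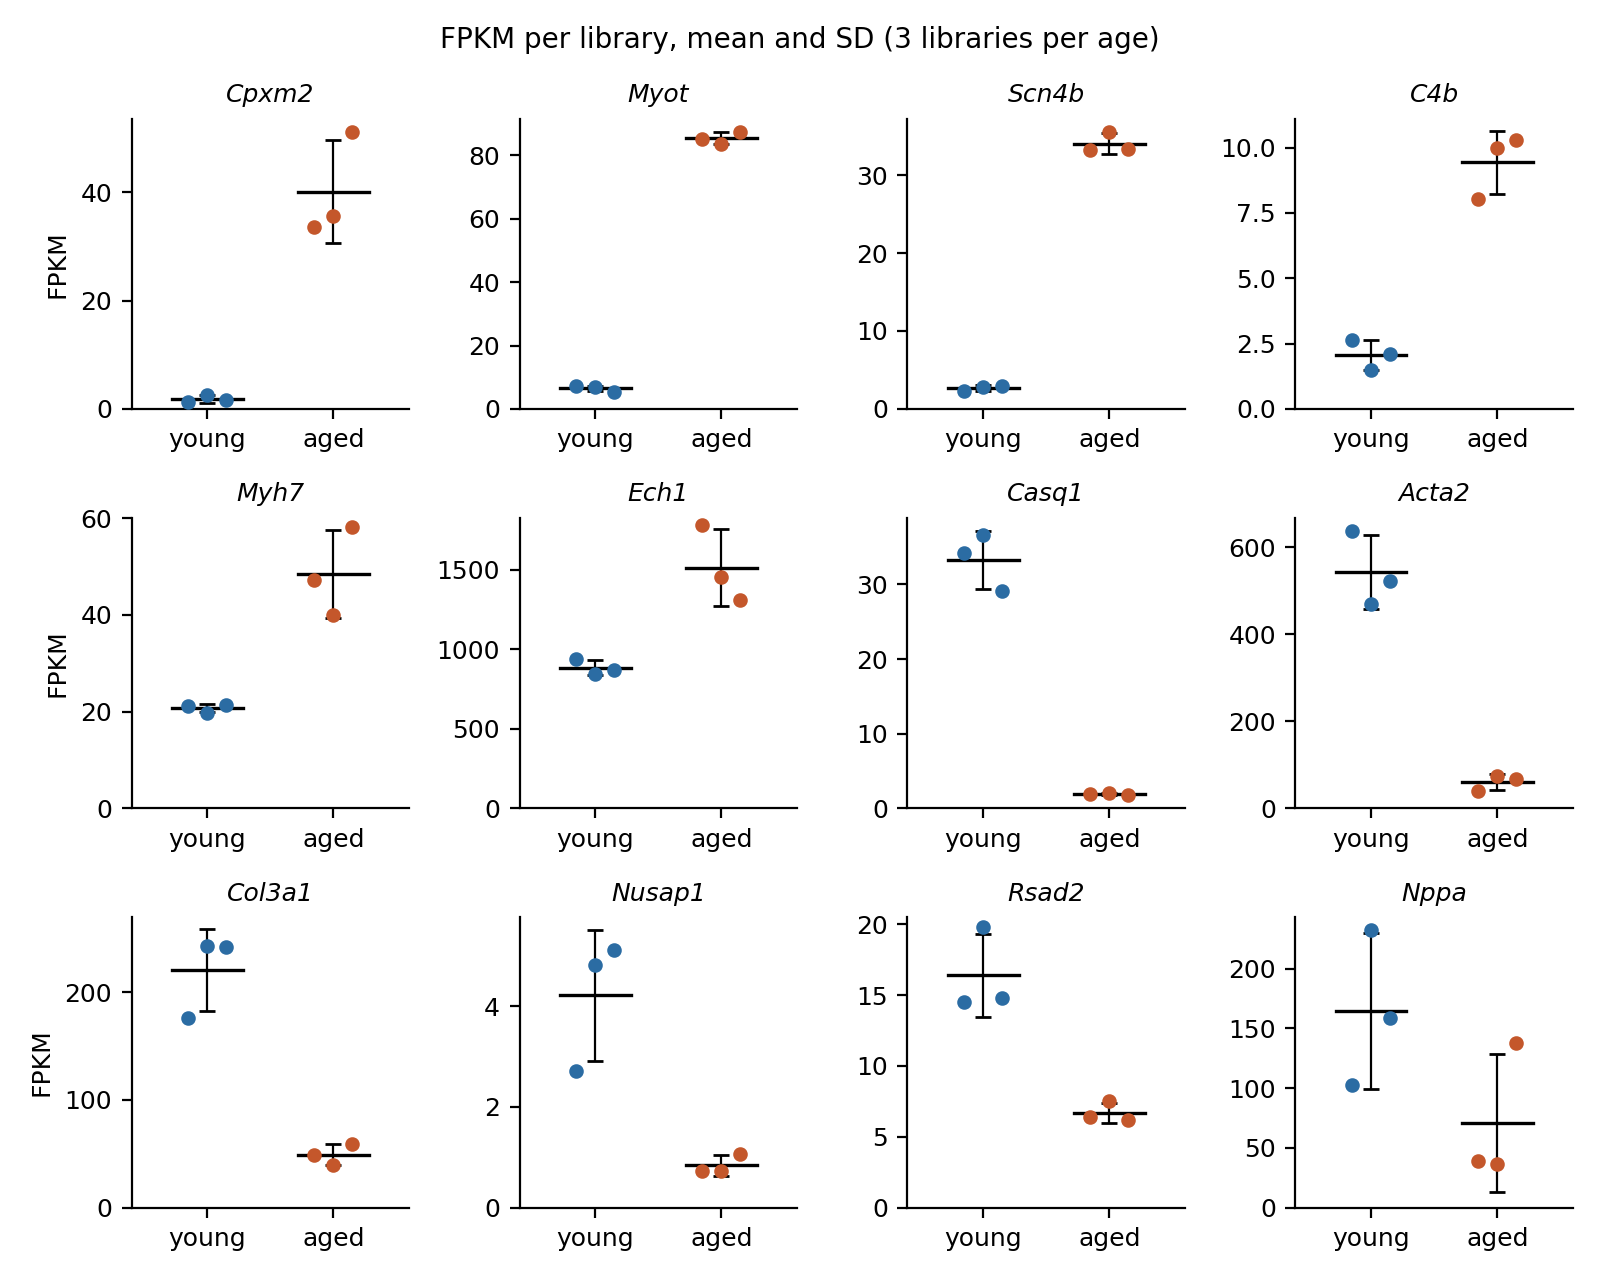
FPKM of 12 named genes in each library (points; blue young, orange aged), with the group mean (line) and SD (bars), 3 libraries per age and each vertical axis starting at 0. In the first 11 panels the ages do not overlap, as in Myot, at 6.44 ± 0.913 in young and 85.5 ± 1.94 in aged; Nppa in aged replicate 3, at 137 FPKM, lies within the young range of 102 to 232.

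Matrix genes fell as a group. Of 38 tested genes of fibrillar collagen and matrix, 28 were lower and 1, the protease gene Mmp3, higher (29 and 2 when adjusted over the list alone). The list had a median log2 difference of -0.85 and camera adjusted p = 3.73e-10; adjusted p = 0.468 with an estimated correlation. Col1a1, a chain of type I collagen, was at 68.1 ± 7.89 FPKM in young and 24.1 ± 4.89 in aged (SD, n = 3; log2 -1.48, SE 0.138, adjusted p = 0.000194). Col3a1 fell from 221 ± 38.1 to 49.01 ± 9.93, Col5a1 from 28.3 ± 1.89 to 9.01 ± 1.08, Sparc, a collagen-binding matrix protein, from 736 ± 132 to 174 ± 30.01, and the collagen chaperone Serpinh1 from 265 ± 6.04 to 129 ± 11.6. In the basement membrane list 16 of 18 genes were lower and Lama5 alone higher (16 and 1 adjusted over the list alone). The basement membrane list had a median log2 difference of -0.98 and camera adjusted p = 3.73e-10, and adjusted p = 0.403 with an estimated correlation. Its examples were Col4a5, 2.65-fold lower (15.7 ± 0.352 to 5.91 ± 0.372), the laminin chain Lamc1, 2.26-fold, the linker Nid1, 2.22-fold, and Col15a1, 3.37-fold. The fall of Col3a1 and that of Col15a1 held in each fit that left out a library. Against aged replicate 3 alone, 20 matrix and 14 basement membrane genes were lower.

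Many markers of vessel wall cells were also lower. Of 19 mural cell markers (pericytes and smooth muscle) 12 were lower and 0 higher (13 lower adjusted over the list alone). The mural cell markers list had a median log2 difference of -0.40 and camera adjusted p = 0.000146, and adjusted p = 0.403 with an estimated correlation. Besides Acta2 they included Myl9, a myosin light chain of smooth muscle (71.1 ± 7.74 to 21.05 ± 3.54 FPKM, SD, n = 3), the pericyte gene Vtn (1.61-fold) and the proteoglycan Cspg4 (1.697-fold). Among 24 endothelial markers 10 were lower and 0 higher, 10 also when adjusted over the list alone, such as Esam (1.64-fold), the cadherin Cdh5 (1.66-fold), the receptor Tie1 (1.505-fold) and the water channel Aqp1 (1.49-fold). The endothelial list did not pass (median -0.23, camera adjusted p = 0.0595), but its adjusted p was 0.0116 without young replicate 1, 0.0382 without young replicate 3, and under 0.05 with each of the 3 other scalings, no filter on low values, a minimum of 5 FPKM, or library quality weights. The fibroblast list did not pass either (median -0.23, camera adjusted p = 0.188; 0.0442 without aged replicate 3): 7 of 23 markers were lower and 2, Dpep1 and Scara5, higher (10 and 3 adjusted over the list alone). Mfap4, a microfibril protein, fell from 58.9 ± 19.6 to 13.4 ± 3.58, Pcolce, an enhancer of procollagen cleavage, 1.54-fold and the matrix protein Dpt 1.33-fold, while the dipeptidase Dpep1 rose 1.91-fold. The fibroblast count was 4 without young replicate 2 or aged replicate 2. Markers of epicardium did not pass as a list (camera adjusted p = 0.52); 2 of 7, Aldh1a2 and Wt1, were lower, also adjusted over the list alone, and 0 without young replicate 3. Markers of Schwann cells and neurons did not pass (camera adjusted p = 0.728, pointing up). Their median was -0.07, and with quantile normalization the median was 0.0075 and the camera adjusted p 0.909. Of 10 markers 3, Pmp22, Dbh and Gfra3, were lower and Mal higher, also adjusted over the list alone.

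Genes of cell division were lower. Of 34 tested cell cycle genes 30 were lower and 0 higher (33 lower adjusted over the list alone). The cell cycle list had a median log2 difference of -1.11 and camera adjusted p = 3.73e-10, and adjusted p = 0.49 with an estimated correlation. Mki67, the proliferation marker, was at 5.31 ± 2.34 FPKM in young and 1.103 ± 0.555 in aged (SD, n = 3; log2 -1.53, SE 0.299, adjusted p = 0.00658). Nusap1, of the mitotic spindle, was at 4.22 ± 1.305 and 0.837 ± 0.202, and the mitotic kinesin Kif23 at 3.89 ± 1.34 and 0.70 ± 0.24. Birc5, which encodes survivin, was at 7.05 ± 2.83 and 1.48 ± 0.202, and the replication helicase subunit Mcm6 at 7.47 ± 1.21 and 3.51 ± 0.427. Fewer members passed, 18, without young replicate 2 or without young replicate 3, and 5 with aged replicate 3 as the sole aged library, where Mki67 did not. Mki67 was at 2.6, 6.67 and 6.65 FPKM in young replicates 1 to 3. Pou5f1, a gene of pluripotent cells named after its values were seen, was at 0.33, 2.62 and 1.79 in these and at 0, 0 and 2.78 in the aged. In the senescence list 10 of 19 genes were lower and 2, among them Gdf15, higher (13 and 2 adjusted over the list alone). The senescence list had a median log2 difference of -0.41 and camera adjusted p = 0.038, and adjusted p = 0.49 with an estimated correlation. Cdkn1a, which encodes the cell cycle inhibitor p21, fell from 51.7 ± 6.05 to 28.2 ± 3.96 FPKM (log2 -0.85, SE 0.112, adjusted p = 0.00112), the nuclear lamin Lmnb1 2.69-fold, and the growth factor binding genes Igfbp7 1.87-fold and Igfbp3 1.45-fold. The loss of Lmnb1, not its rise, is used as a senescence marker, so the direction of the list does not measure senescence. Cdkn2a, the locus of the inhibitor p16, was below the level for testing, at 0, 0.13 and 0.23 FPKM in the young libraries and 1.34, 1.18 and 0.88 in the aged. Cdkn2b, also below that level, was at 0.47, 0.24 and 0.28 in young and 0.8, 0.56 and 0.84 in aged. The ages did not overlap for either gene, but 3 against 3 cannot give an exact permutation p below 0.1. The senescence list lost its call on TPM (adjusted p = 0.11), with no filter on low values (0.109) and without aged replicate 1 (adjusted p = 0.0868) or 2 (0.0637), and against aged replicate 3 alone (0.347).

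Many genes of fuel use were higher. Of 42 genes of fatty acid oxidation and lipid handling 22 were higher and 2 lower (26 and 2 adjusted over the list alone). The fatty acid oxidation and lipid handling list had a median log2 difference of 0.24 and camera adjusted p = 6.44e-10, and adjusted p = 0.403 with an estimated correlation. Ech1, an enzyme of mitochondrial beta-oxidation, rose from 884 ± 48.8 to 1512 ± 241 FPKM (SD, n = 3; log2 0.76, SE 0.105, adjusted p = 0.0014). Acat1, of ketone and isoleucine breakdown, rose 1.37-fold and the lipase gene Lpl 1.33-fold, with a log2 difference for Lpl of 0.41 that quantile normalization brought to 0.25. The lower members were the uncoupling protein gene Ucp2 (91.1 ± 2.905 to 43.9 ± 5.47) and Pdk4, an inhibitor of pyruvate oxidation. Among 31 genes of glycolysis and glucose use 12 were higher and 3, Pfkp, Pgk1 and Eno3, lower (15 and 4 adjusted over the list alone). The glycolysis and glucose use list had a median log2 difference of 0.16 and camera adjusted p = 0.000349, and adjusted p = 0.403 with an estimated correlation, and 0.0624 with quantile normalization. Pfkfb1, a regulator of glycolytic flux, rose 3.71-fold, Pdk1 1.56-fold, the lactate dehydrogenase subunit Ldhb 1.302-fold and the insulin-responsive glucose transporter Slc2a4 1.27-fold. Against aged replicate 3 alone 7 fatty acid genes and 6 glycolysis genes were higher.

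Nuclear genes of oxidative phosphorylation moved little. Of 73 subunits 9 were higher and 0 lower, but 1 was higher when adjusted over the list alone (median 0.08, camera adjusted p = 1.43e-05; adjusted p = 0.563 with an estimated correlation). The list turned to lower, without a call, under quantile normalization (median -0.01, 2 higher and 2 lower) and after removal of each library's trend on transcript length and GC content (-0.05, 15 lower). The gene Cox6a2, for the muscle form of a cytochrome oxidase subunit, was at 3729 ± 182 FPKM in young and 5152 ± 568 in aged (SD, n = 3; log2 0.46, SE 0.0854, adjusted p = 0.00529), but its call ended with the length and GC correction. The count was 1 without young replicate 3, 2 without aged replicate 1, 3 without young replicate 1 or 2 and 5 without aged replicate 3, and 17 with median-of-ratios scaling. In the list of sirtuins and NAD metabolism 6 of 19 genes were higher and Cd38, an NAD-consuming enzyme, lower (6 and 1 adjusted over the list alone). The list had a median of -0.03 (0.03 with median-of-ratios scaling and 0.05 with quantile normalization) and a mean of 0.10, while camera pointed up (adjusted p = 0.045; adjusted p = 0.403 with an estimated correlation). That call was lost with no filter on low values (adjusted p = 0.12), on TPM (0.0735), with median-of-ratios scaling (0.0528), a prior variance without a trend (0.0508) or a replicate block (0.065), and after the length and GC correction (0.062). It was also lost without young replicate 2 (adjusted p = 0.053), aged replicate 1 (0.057) or aged replicate 2 (0.0542), and against aged replicate 3 alone (0.0592). Nampt, which makes the NAD precursor NMN, rose from 38.5 ± 0.8601 to 61.2 ± 3.14, Nmnat3 1.46-fold and the muscle kinase Nmrk2 2.21-fold. RNA of Nnt, the mitochondrial transhydrogenase that some C57BL6 substrains lack, was present in all 6 libraries, at 113 ± 2.25 in young and 154 ± 0.537 in aged (log2 0.45, SE 0.0503, adjusted p = 0.000503). A value for the whole gene does not show whether its sequence is intact, so it does not tell the substrain.

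The 4 genes with the largest statistics in the antioxidant list were glutathione transferases. Of 29 antioxidant genes and NRF2 targets 13 were higher and 2, Gpx1 and Ucp2, lower (14 and 2 adjusted over the list alone). The antioxidant and NRF2 targets list had a median log2 difference of 0.12 and camera adjusted p = 4.46e-06, and adjusted p = 0.403 with an estimated correlation. The glutathione transferase Gstm1 rose from 154 ± 7.94 to 290.3 ± 4.201 FPKM (SD, n = 3; log2 0.91, SE 0.0571, adjusted p = 2.71e-05), Gstm2 2.27-fold, Gsta4 1.94-fold and the microsomal form Mgst1 2.82-fold; transferase genes have close copies, between which reads can be split. Of 33 genes of autophagy and mitophagy 7 were higher and Trim63, a muscle ubiquitin ligase gene, lower (7 and 1 adjusted over the list alone). The autophagy and mitophagy list had a median log2 difference of 0.09 and camera adjusted p = 0.00294, and adjusted p = 0.403 with an estimated correlation. They included the mitophagy kinase Pink1 (225 ± 15.4 to 351 ± 9.02), the mitophagy receptor Bnip3 (1.7-fold), the lysosomal protease Ctsd (1.52-fold) and Gabarapl1 (1.69-fold).

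Part of the sarcomere list was higher. Of 24 tested, 8 were higher and 0 lower (8 and 1 adjusted over the list alone, and 6 and 2 on TPM), and the others did not pass. The sarcomere list had a median log2 difference of 0.16 and camera adjusted p = 0.00179, and adjusted p = 0.403 with an estimated correlation, and 0.184 with quantile normalization. The ventricular light chain gene Myl2 went from 11761 ± 529.6 to 17061 ± 1127 FPKM (SD, n = 3; log2 0.54, SE 0.0739, adjusted p = 0.0014), but the call was lost with quantile normalization (0.18) or no filter on low values. The titin-cap gene Tcap rose 1.498-fold, the chaperone Cryab 1.29-fold and troponin T gene Tnnt2 1.25-fold. The sarcomere count was 4 without young replicate 2 or 3, 5 without aged replicate 2, 13 with median-of-ratios scaling and 5 with quantile normalization. The hypertrophy markers, fetal-type genes that rise in overloaded hearts, did not pass as a list (4 of 15 higher and 2 lower, 4 and 3 adjusted over the list alone). Their median was 0.17 but their mean -0.03, with camera up at adjusted p = 0.201, and 0.00196 with aged replicate 3 as the sole aged library. Without young replicate 2 or 3 the higher members numbered 2, and without aged replicate 3 there were 2 higher and 6 lower. Myh7, the slow myosin heavy chain, rose from 20.8 ± 0.888 to 48.5 ± 9.097 (log2 1.17, SE 0.118, adjusted p = 0.000289) and Xirp2 1.31-fold, with Xirp1 and Gdf15 the other higher members, and Actn1 (1.73-fold) and Mybpc2 (2.06-fold) fell. Myh6, the main heavy chain of adult mouse ventricle, was at 6368 ± 515 and 5855 ± 227 (adjusted p = 0.275), and the calcium pump Atp2a2 at 3246 ± 237 and 3536 ± 179.5 (adjusted p = 0.242).

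The natriuretic peptide genes varied widely within an age. The atrial peptide gene Nppa was at 102, 232 and 159 FPKM in the young libraries and 38.9, 36.3 and 137 in the aged (log2 -1.41, SE 0.474, adjusted p = 0.0568); it passed without aged replicate 3 (-2.02), without young replicate 1 (-1.71) and on TPM (-1.46). Nppb was at 347 ± 145 and 461 ± 148 (SD, n = 3; adjusted p = 0.323) and skeletal actin gene Acta1 at 630.3 ± 209.8 and 385 ± 229 (adjusted p = 0.151), with a pass for Acta1 without aged replicate 3 (log2 -1.25). Calcium handling and ion channel genes moved both ways, 5 of 29 higher (with Cacna1c and Kcnj3) and 5 lower (with Camk2d and Hcn2; 6 and 6 adjusted over the list alone; median 0.04, camera adjusted p = 0.277). Besides Scn4b, the calcium-binding gene Hrc rose 1.27-fold, while the potassium channel genes Kcna5 (22.4 ± 3.69 to 7.71 ± 1.09) and Kcnd2 (1.54-fold) fell. The count of higher members was 3 without young replicate 3 or aged replicate 2, and the median was -0.05 without young replicate 2 and -0.06 without aged replicate 2. Atrial markers did not pass as a list (3 of 11 higher, 3 higher and 2 lower adjusted over the list alone; camera up at adjusted p = 0.398, and 0.0443 with a minimum of 5 FPKM, against a median of -0.11). Stard10 rose 1.72-fold, and the others, Kcnj3 and Tbx5, brought the count to 3, which was 1 without young replicate 2 or 3 or aged replicate 1 or 2. Skeletal muscle markers did not pass either (1 of 6 higher and 2 lower, also over the list alone; camera adjusted p = 0.411, pointing down, and up on TPM and without aged replicate 3, where 2 were higher). Besides Casq1, Myl1 was 1.97-fold lower, and Cacna1s, the skeletal calcium channel, went from 1.25 ± 0.175 to 4.96 ± 0.965. The skeletal myosins Myh1, Myh2 and Myh4, named after their values were seen, stayed at or below 0.26 FPKM in every library. These low values do not exclude a trace of skeletal muscle RNA. Tnnc2, chosen in the same way, was at 1.06, 2.02 and 0.19 FPKM in aged replicates 1 to 3, and Tnnt3 at 1.58, 2.2 and 0.92. Both were highest in the libraries with keratin transcripts, whereas Myh2 and Myoz1 were highest in young replicate 3.

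Part of the complement list was higher. Of 16 tested, 8 were higher and Masp1 lower (8 and 2 adjusted over the list alone). The complement list had a median log2 difference of 0.21 and camera adjusted p = 0.0026, and adjusted p = 0.473 with an estimated correlation. C4b, a component of the classical pathway (chromosome 17, 34728139 to 34743902, GRCm38), rose from 2.08 ± 0.575 to 9.44 ± 1.21 FPKM (SD, n = 3; log2 1.77, SE 0.148, adjusted p = 0.000105). C3, the central component, rose from 16.7 ± 8.45 to 94.7 ± 6.82, and the proteases C1s1 1.76-fold and C1ra 1.61-fold. The genes of the C1q chains were not called, with log2 differences as deposited of -0.07 (C1qa), -0.15 (C1qb) and -0.24 (C1qc). Among 27 chemokines and cytokines 11 were higher and 5, Cxcl9, Cxcl10, Il16, Tgfb3 and Csf1, lower (11 and 6 adjusted over the list alone). The chemokines and cytokines list had a median log2 difference of 0.23 and camera adjusted p = 0.00115, and adjusted p = 0.403 with an estimated correlation. The eosinophil attractant Ccl11 rose from 0.343 ± 0.0945 to 6.98 ± 1.59, Cxcl14 from 5.497 ± 1.28 to 25.9 ± 3.26 and fractalkine, Cx3cl1, 1.91-fold. Without aged replicate 2 there were 7 higher members, and without it, young replicate 2 or aged replicate 1 there were 3 lower. In the antigen presentation list 5 of 22 genes were higher, all of class II presentation, and 0 lower (6 and 1 adjusted over the list alone). The antigen presentation list had a median log2 difference of 0.11 and camera adjusted p = 0.00373, and adjusted p = 0.56 with an estimated correlation. H2-Aa went from 36.7 ± 18.7 to 94.5 ± 10.4, H2-Eb1 from 16.2 ± 6.95 to 42.1 ± 6.21, H2-Ab1 from 28.2 ± 12.2 to 69.2 ± 9.37 and the invariant chain Cd74 from 99.8 ± 48.03 to 216 ± 24.5, and H2-DMb1 was the fifth. The list did not pass without aged replicate 2 (adjusted p = 0.0637), its median was -0.0040 without young replicate 3, and against aged replicate 3 alone 1 gene passed.

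Interferon-stimulated genes were lower. Of 40 tested, 24 were lower and Gbp6 higher (30 and 1 adjusted over the list alone). The interferon-stimulated genes list had a median log2 difference of -0.57 and camera adjusted p = 7.38e-07, and adjusted p = 0.49 with an estimated correlation. The antiviral gene Rsad2 fell from 16.4 ± 2.96 to 6.68 ± 0.722 FPKM (SD, n = 3; log2 -1.17, SE 0.123, adjusted p = 0.000351), and the signalling genes Irf9 and Stat2 1.73-fold and 1.77-fold, with Trim30a 1.697-fold lower. The count was 15 without young replicate 2 or aged replicate 1, and 13 against aged replicate 3 alone. Macrophage markers did not move as a list: of 25, 4 were higher (Ccr2, Gpnmb, Lgals3, Ly6c2) and 4 lower (5 and 5 adjusted over the list alone; median -0.15, mean 0.01, camera adjusted p = 0.568). The fractalkine receptor Cx3cr1 fell from 5.74 ± 0.315 to 1.67 ± 0.469, the growth factor receptor Csf1r 1.47-fold and the mannose receptor Mrc1 1.41-fold; Laptm5 was the fourth. Lgals3, which encodes galectin 3, rose from 3.24 ± 0.509 to 10.1 ± 5.03. Without young replicate 2 or aged replicate 2 the higher markers numbered 2.

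Lymphocyte markers were near the floor. The table held 13 of 24 listed B and plasma cell genes and 25 of 28 T and NK cell genes. None of the listed immunoglobulin genes was in it, nor were Trac, Trbc1 and Trbc2. The B and plasma cell list therefore says little of antibody-secreting cells. With 4 B and plasma cell markers and 2 T and NK cell markers tested, 0 of either were called by limma, over all genes, adjusted over the list alone or at an unadjusted p under 0.05. With no filter on low values 1 of 13 B and plasma cell markers was higher, and of 25 T and NK cell markers 1 was higher and 1 lower, and on TPM 1 of 10 T and NK cell markers was lower. The B cell gene Cd79a was at 1.803 ± 0.652 FPKM in young and 1.19 ± 0.342 in aged (SD, n = 3; limma adjusted p = 0.227) and the plasma cell gene Sdc1 at 3.39 ± 0.0379 and 3.22 ± 0.667 (adjusted p = 0.727). The T cell receptor gene Cd247 was at 1.65 ± 0.762 and 1.95 ± 0.225 (adjusted p = 0.516). Neutrophil markers passed as a list of 5 tested genes (3 higher, 4 adjusted over the list alone; camera adjusted p = 0.0181; adjusted p = 0.403 with an estimated correlation, 0.0582 with quantile normalization and 0.109 with no filter on low values). The calprotectin gene S100a8 was at 17.4, 26.9 and 2.91 FPKM in aged replicates 1 to 3, against 0.61, 3.13 and 0.27 in young. Its partner gene S100a9 was at 33.4, 40.2 and 3.15 against 1.32, 4.07 and 0.4. Both are also abundant in stratified epithelium and were high in the libraries that held Krt13. Neither passed without young replicate 1 or 3 or aged replicate 1 or 2 (adjusted p = 0.0599 to 0.0818 for S100a8 and 0.0736 to 0.111 for S100a9). The gene Lcn2 was lost without young replicate 1 or 3 or aged replicate 1 or 3 (0.0539 to 0.124). The list counted 1 higher gene without young replicate 1 or 3 or aged replicate 1, another than these, and 1 without aged replicate 2. Erythroid genes, from blood in the tissue, were lower in 8 of 10 cases and higher in 2, Fech and Tspan33 (the same 8 and 2 adjusted over the list alone). The erythroid markers list had a median log2 difference of -0.81 and camera adjusted p = 0.00469, and adjusted p = 0.49 with an estimated correlation. Globin gene Hba-a2, which has a near-identical copy, was at 5059.7 ± 1064 and 2537 ± 236, Hbb-bt at 929 ± 128 and 441 ± 68.8, and the haem synthesis gene Alas2 at 62.7 ± 13.1 and 32.5 ± 0.547.

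Adipocyte markers moved both ways, 4 of 11 higher (Plin4, Scd1, Pparg, Thrsp) and 3 lower (Pnpla3, Fasn, Aoc3), also over the list alone (median 0.12, mean -0.02, camera up at adjusted p = 0.301). The amine oxidase Aoc3 fell from 11.7 ± 1.79 to 5.58 ± 0.571 FPKM (SD, n = 3), and Pparg, a regulator of fat cell formation, went from 5.69 ± 0.656 to 8.25 ± 0.615. Of 23 immediate early genes 5 were higher and 2 lower (9 and 3 adjusted over the list alone). The immediate early genes list had a median log2 difference of 0.11 and camera adjusted p = 0.0109, and adjusted p = 0.49 with an estimated correlation. Egr1 rose from 7.65 ± 1.46 to 19.9 ± 6.39, Jun 1.53-fold and Junb 1.84-fold, and Klf6 fell 1.53-fold, with Fos and Egr3 also higher and Klf2 lower. Without young replicate 1 the higher members numbered 9, and without young replicate 3 or aged replicate 1 they numbered 3. The clock list was level (4 of 20 higher and 3 lower, also adjusted over the list alone). Its median was 0.01, and -0.03 on TPM, its mean -0.02, and camera pointed up (adjusted p = 0.378). The clock repressor Per1 fell from 21.2 ± 2.34 to 6.91 ± 1.05 (log2 -1.49, SE 0.114, adjusted p = 7.01e-05) and Bhlhe40 1.45-fold, while Bhlhe41 rose 1.53-fold. Cry2 and Tef were also higher and Npas2 lower.

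Protein folding genes showed no list call. Of 24 heat shock genes and chaperones 5 were higher and Stip1 lower (6 and 1 adjusted over the list alone). Their median was -0.05, and 0.01 with median-of-ratios scaling, with a mean of 0.11 and camera up (adjusted p = 0.159). The small heat shock gene Hspb7 rose 1.39-fold and the cochaperone Bag3 1.42-fold, with Hspa1l, Hspb6 and Hspb8 also higher. Without aged replicate 1 the list passed (adjusted p = 0.00192, 9 higher), as it did against aged replicate 3 alone (0.000295), and without young replicate 3 or aged replicate 3 the higher members numbered 3. In the unfolded protein response list 8 of 23 genes were lower and 3, Dnajb9, Herpud1 and Atf6, higher (10 and 3 adjusted over the list alone; median -0.25, camera adjusted p = 0.126, 0.0233 without young replicate 2 and 0.0364 with no filter on low values). The disulfide isomerase Pdia3 fell from 89.4 ± 1.61 to 67.4 ± 2.88 FPKM (SD, n = 3), Pdia6 1.36-fold and calreticulin, Calr, 1.25-fold, whereas Herpud1 rose 1.31-fold. Without young replicate 3 or aged replicate 1 the lower members numbered 5. Cytosolic ribosomal protein genes moved little, 3 of 71 higher and 2 lower (1 and 0 adjusted over the list alone). There was 1 higher without young replicate 1 or 3 or aged replicate 1, 1 lower without young replicate 3 or aged replicate 1 or 2, and 0 lower without young replicate 2. The list turned to lower under quantile normalization (median -0.0038) and after the length and GC correction (median -0.10, 18 lower), while median-of-ratios scaling gave 10 higher and 0 lower. The cytosolic ribosomal proteins list had a median log2 difference of 0.05 and camera adjusted p = 0.00276, and adjusted p = 0.646 with an estimated correlation. Its call was lost without young replicate 1 (adjusted p = 0.0653) or aged replicate 1 (0.133). Rps13 rose 1.25-fold, with Rps21 also higher, while the gene Rps2 fell 1.18-fold, with Rpl3 also lower. The fall of Rps2 was not called with median-of-ratios scaling (log2 -0.17) or without young replicate 2 (-0.22), and the gene Rps21 turned to lower after the correction (-0.17).

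**Figure D3:**
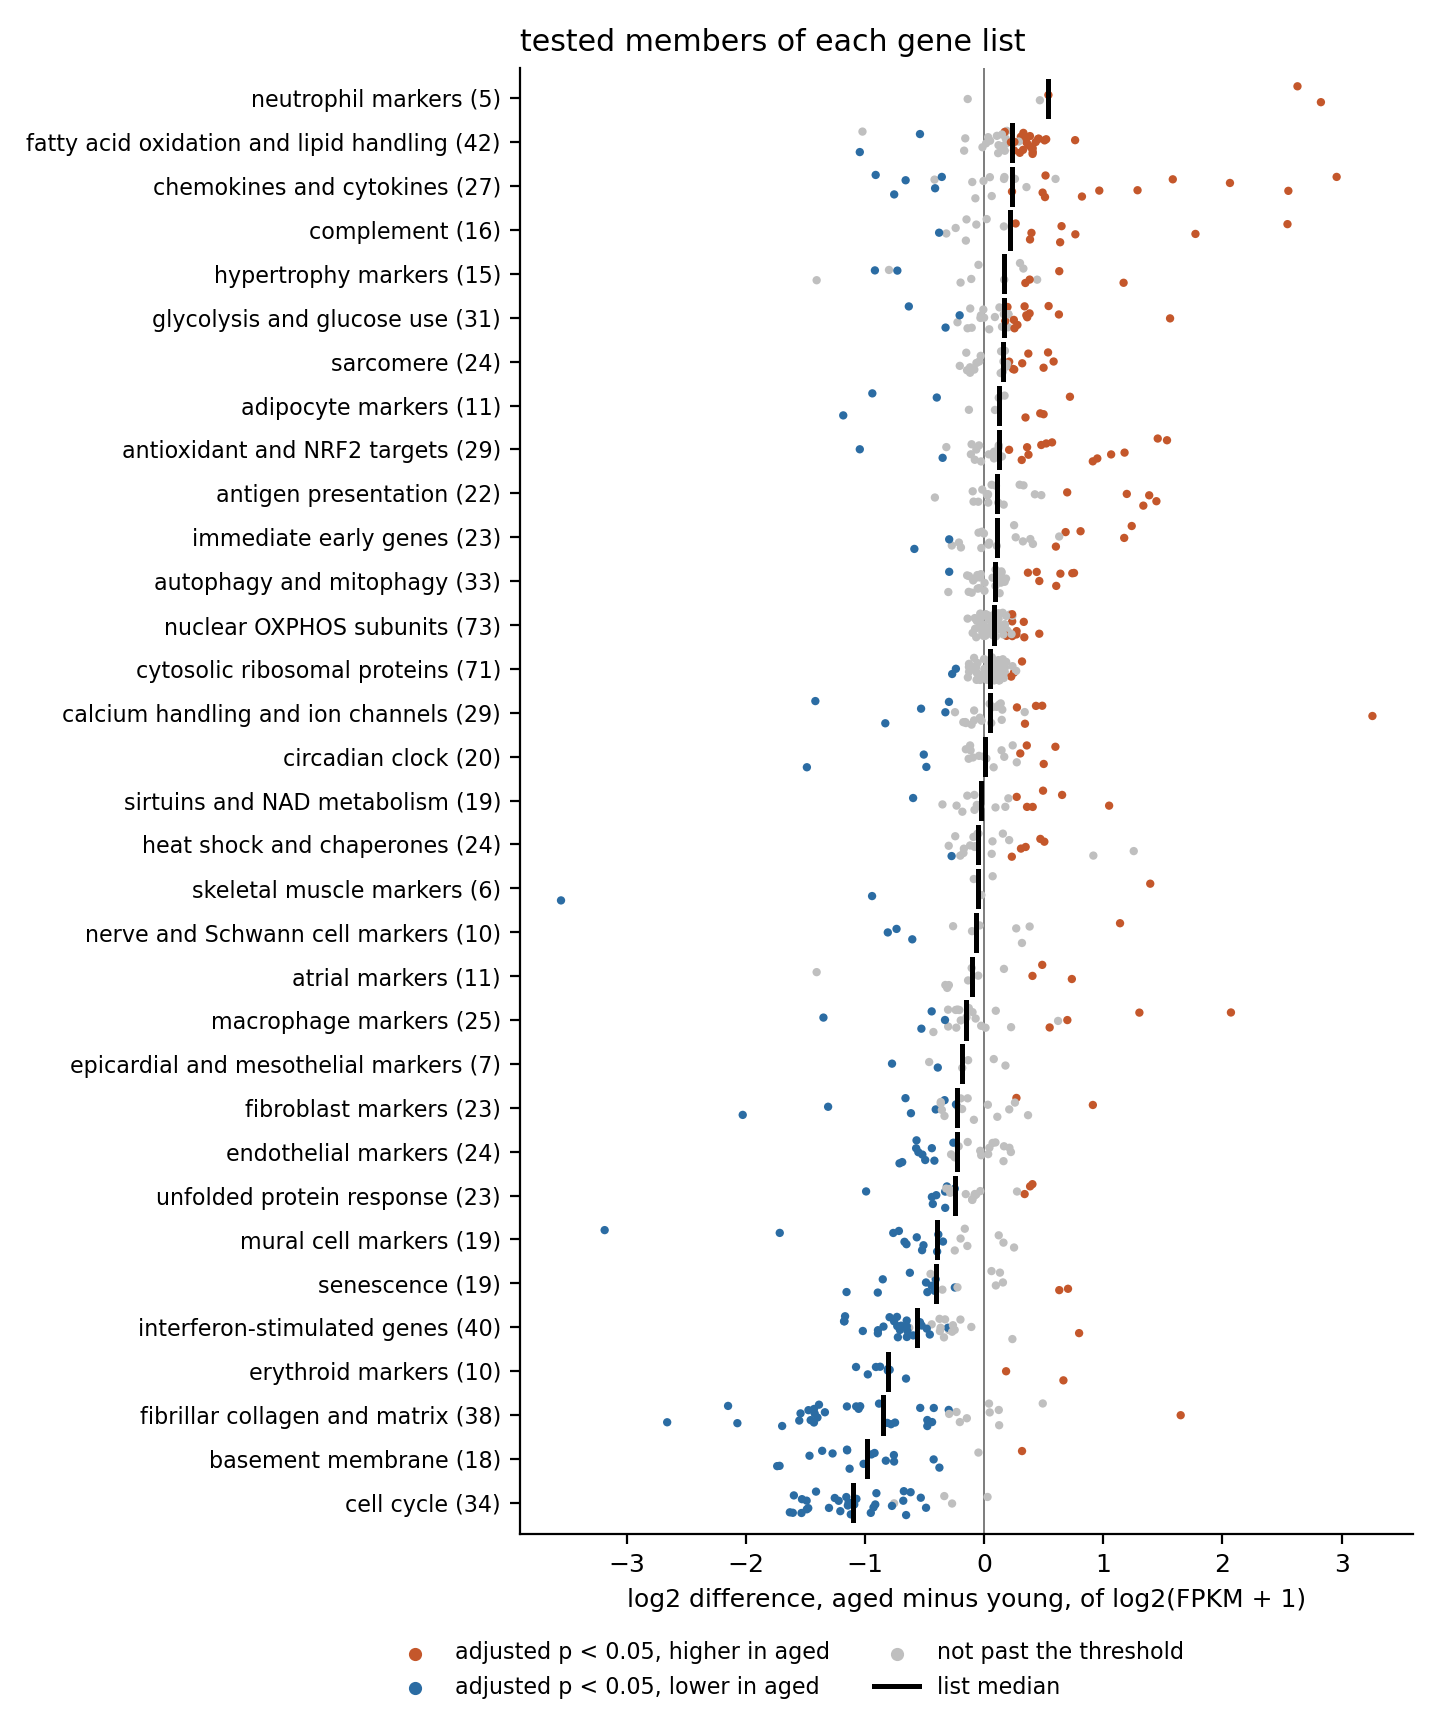
Log2 difference, aged minus young, of log2(FPKM + 1) for each tested member (point) of the 33 lists with at least 5 tested members, the number tested in brackets; orange points were higher and blue points lower at an adjusted p under 0.05, grey points did not pass, and black bars are list medians. Cell cycle, basement membrane and matrix lists lie lowest, with medians of -1.11, -0.98 and -0.85; the oxidative phosphorylation and ribosomal lists, near 0, change sign under quantile normalization.

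Of the 33 lists tested, 20 passed with the preset correlation of camera, 13 higher and 7 lower. Other splits of the 6 libraries into groups of 3 called 8 to 16 lists, against 20 for the ages. For single genes limma called 0 in the other splits, with 121 to 504 at an unadjusted p under 0.05 against 4609 for the ages. Each other split mixes the ages within its groups, so the age difference widens its spread and lowers its calls. Such splits do not show what chance gives, for genes or for lists.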

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

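The tests with a length and GC correction, without both aged replicates 1 and 2, and without genes specific to these were chosen after seeing the data. Leaving out 1 library at a time gave 718 to 1020 higher and 1164 to 1958 lower genes. With aged replicate 3 as the sole aged library, assumed to vary like the others, 420 were higher and 552 lower, of which 389 and 520 were shared with the calls from all libraries; fewer samples entered. A minimum log2 difference of 1 left 140 and 160 by construction. Lists past the threshold numbered 16 to 21 over the settings that refit the genes, and 0 with estimated correlations, which allow for members that vary together. The replicate number as a block gave 1002 higher and 1783 lower genes and 19 lists. The numbers did not pair the samples: deviations of equally numbered libraries correlated at 0.041, -0.08 and 0.038, and only replicate 1 correlated best with its own number.

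The cause of the reversals was not tested. The skeletal muscle list turned with no filter (median 0.0746), on TPM (-0.0171, by camera's direction) and without aged replicate 3, and by its median alone without young replicate 3 (0.0287); leaving out 1 library gave -0.1155 to 0.2317. For the nerve list (median -0.0709) camera's direction turned from up to down with no filter (-0.039), on TPM (-0.1484) and against aged replicate 3 alone (-0.0933), while its median changed sign with quantile normalization (0.0075), a minimum of 5 FPKM (0.1391) and without young replicate 2 (0.0149). Quantile normalization turned oxidative phosphorylation (-0.0124) and ribosomal genes (-0.0038), and so did the length and GC correction (-0.0507 and -0.1009), which also turned the gene Cox8b (0.33 to -0.1591) and the gene Rps21 (0.23 to -0.1658), both called before. The clock list (median 0.0062) pointed down with fry. The gene Ddx3y turned on TPM (-0.0123) and without aged replicate 2, with a range of -0.001 to 0.0578 when 1 library was left out. The gene Eif2s3y turned with median-of-ratios scaling (0.0533), quantile normalization (0.0231), against aged replicate 3 alone (0.0103), and without young replicate 2 or 3 or aged replicate 2, with a range of -0.0707 to 0.0486. The gene Sdc1 turned with quantile normalization (0.0105) and without aged replicate 3, with a range of -0.139 to 0.0701. The gene Acta1 turned against aged replicate 3 alone (-0.80 to 0.103).

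Of the other settings of single named genes, 2753 kept direction and side of the threshold, 123 lost the call, 11 gained it and 13 reversed; for lists the numbers were 645, 47, 18 and 11. Depth is unknown, so it is not known which low genes the sequencing could have shown to differ.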

Other observations

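The tests of cell cycle genes against pluripotency transcripts, of fibroblast and smooth muscle markers against matrix genes, and both tests of the place of aged replicate 3 were chosen after the result was seen, and the bounds on what the cell cycle and smooth muscle tests can exclude were tightened after their values were known. The count of detoxification enzymes without glutathione transferases and the place of Lcn2 in the neutrophil test were also chosen after the result was seen. The other tests were fixed before their result was computed, but the additional lists were chosen after the genes that prompted them had been seen.

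Aged replicates 1 and 2 held transcripts of stratified epithelium. Besides Krt13, Krt4 was at 34.6 and 59.1 FPKM and Krt14 at 40.3 and 64.4 in them, with both listed at 0 in aged replicate 3, and 26 of 29 listed epithelial genes (89.66%, where chance gives 6.67%) were higher in both than in each other library; 4 of the list's genes have a young mean of at least 1 FPKM and 0 are in the fixed lists, so epithelial RNA is a candidate source. Neutrophils as a further source stay open. Of neutrophil genes other than S100a8 and S100a9, 18.75% (3 of 16) followed, all 16 from the fixed neutrophil list and 2 with a young mean of at least 1 FPKM. Only 3 of the 16 reached the level for testing, so a count over genes near the floor cannot decide. By the bound fixed before the result was computed, the share counted against neutrophils, a reading not kept here for that reason. The highest of those that followed was Clec4d at 2.95 FPKM. Lcn2 was higher in aged replicate 3 (4.66) than in aged replicates 1 and 2 (3.77 and 2.96). Pou5f1, a gene of pluripotent cells, was at 0.33, 2.62 and 1.79 FPKM in young and 0, 0 and 2.78 in aged libraries, and 37.04% of the pluripotency list (10 of 27, where chance gives 10%; 2 have a young mean of at least 1 FPKM and 0 are in the fixed lists) were higher in those 3 libraries than in aged replicates 1 and 2, which leaves such RNA open. As the source of the cell cycle difference it also stays open: cell cycle genes in aged replicate 3 lay at a median of -1.129 (95% interval -1.36 to -0.85) from young replicates 2 and 3 despite its Pou5f1, but that rests on 1 aged library. Young replicate 1, with little Pou5f1, also lay above aged replicate 3, by 0.336. That goes against such a source as the whole cause. The gap was smaller than that of young replicates 2 and 3, which goes with such RNA as a part, and both rest on the same aged library.

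Matrix and basement membrane genes were lower, with a median of -0.93 over 56 tested. A lower share of fibroblasts as the whole cause is argued against by the fibroblast markers, whose median lay 0.709 above (95% interval over genes 0.42 to 0.99). That interval does not measure the spread between samples. The markers include genes of matrix proteins, such as Mfap4 and Dpt. Smooth muscle of large vessels in the young pieces cannot be told apart. Its genes lay 0.771 above (0.49 to 1.32; 9 tested, 2 higher and 2 lower, 8 of the list in fixed lists and 8 with a young mean of at least 1 FPKM), but Acta2 and Myl9, both lower, were left out of them. The higher genes were Hspb6 and Synpo2, at 1091 ± 26.4 and 30.1 ± 5.398 FPKM in young (SD, n = 3), levels that would hide a small share, and the lower were Tagln and Mylk. Length or GC bias as the whole cause is argued against because 100% of the 44 lower members stayed called after its removal, with 94.5% of their median kept (-1.14 to -1.08). Age itself, and a change within fibroblasts, stay open and untested.

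Aged replicate 3 lay between the other aged libraries and the young ones, at 0.327 of the way on the first component, 0.231 without the listed epithelial genes and 0.0493 without genes specific to the other aged libraries as well, a choice that used aged replicate 3. Young RNA mixed into it cannot be told apart: 15 genes at least 8 times higher in young gave a median share of 0.061, but with an interval of 0.0048 to 0.99. The 111 genes at least 4 times higher gave 0.128, with quartiles of 0.024 and 0.22, below the place of 0.327. Epithelial RNA in the others as the whole cause is argued against by genes that such RNA cannot lower. There aged replicate 3 lay at 0.186 of the way from the other aged libraries to young. By the same measure aged replicates 1 and 2 lay at -0.0305 and -0.0408, a gap of 0.222 (95% interval 0.173 to 0.262). Each place has its own zero and genes. The zeros for aged replicates 1 and 2 include aged replicate 3, which can widen the gap. A biological difference between the aged samples was not tested.

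The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05: 1 split, the real one, gave as many higher genes (1105, highest other 0), 1 as many lower (2026, highest other 0), and 1 as many lists (20, highest other 16). The other splits mix the ages within each group, which widens their spread, so their 0 genes were likely from the start and decide nothing.

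Imprinted growth genes may have been lower in part because the young mice were nearer to growth, a hypothesis raised by Igf2, which fell from 36.01 ± 0.957 to 9.23 ± 1.39 FPKM (SD, n = 3). The other listed genes had a median of -0.345, with 5 of 11 lower and 1 higher. Limma's camera gave p = 0.217 and, with an estimated correlation, 0.265. The hypothesis stays open. Whether nearness to growth also bears on the matrix and cell cycle genes was not tested. A test would compare mice at several ages between 6 to 8 weeks and 24 to 26 months.

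A lower glucocorticoid response in the aged mice is a candidate explanation for the falls of Per1 and Cdkn1a. The median of 18 other induced genes was -0.501, with 11 lower and 2 higher, and 7 of them are in the fixed lists. Limma's camera gave p = 0.00195 and, with an estimated correlation, 0.0469. Both are unadjusted, for a list chosen after the data had been seen, unlike the adjusted values of the fixed lists. Tsc22d3, a widely used reporter of the receptor, fell from 52.7 ± 6.34 to 25.8 ± 2.64 FPKM and Ddit4 from 48.2 ± 3.79 to 22.4 ± 3.84 (SD, n = 3). Of the other members, Fkbp5 (log2 0.11), Zbtb16 (-0.10), Mt2 (-0.32), Dusp1 (-0.20) and Angptl4 (-1.02) were not called, and Mgst1 (1.46) and Lcn2 (0.54) were higher. Hsd11b1, which is not in the list, encodes an enzyme that makes active glucocorticoid. Its rise, from 4.92 ± 1.23 to 20.9 ± 1.65 FPKM, goes the other way. Corticosterone in blood taken at a fixed hour would test a lower response, since time of day and handling are not given.

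Detoxification enzymes may have risen more widely than the glutathione transferases. Cyp2b10 was at 0.15 ± 0.123 FPKM in young and 6.24 ± 1.33 in aged (SD, n = 3), Fmo2 at 2.94 ± 0.188 and 13.6 ± 1.95, and Hsd11b1 at 4.92 ± 1.23 and 20.9 ± 1.65. The 28 other enzymes tested had a median of 0.368, with 17 higher and 1 lower. Limma's camera gave p = 2.66e-12 for them and, with an estimated correlation, 0.00807, both without adjustment. Without the antioxidant list, which holds 4 of them, and without other glutathione transferases, 9 of 19 were higher and 1 lower (median 0.32), and camera gave p = 4.75e-06 and, with an estimated correlation, 0.0182. Enzyme activities in ventricle free of other tissue would test it.

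Of other tissues, 1 of 14 hepatocyte genes, 0 of 6 salivary gland and pancreas genes and 1 of 6 kidney genes were higher in both aged replicates 1 and 2 than in each other library. Of 4 hepatocyte genes tested 1, Ass1, was higher in aged. Skeletal muscle genes were not counted in this way.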
